A study of Homo sapiens with 6 samples.

How the data were processed

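LNCaP cells, an established human prostate cancer line, were treated with siRNA to PCARNEQ or to EGFP, and each group was measured on 3 single-colour arrays. Total RNA was extracted with Trizol and purified on a column, and biotin-labelled cRNA was made by the standard Affymetrix protocol, per the labels. The deposited values are probe-set intensity on a linear scale, summarised with RMA (robust multi-array average), per the submitters' processing notes, with no version given there. RMA corrects background, normalizes by quantiles and summarises the probes of a set. The sorted log2 values of the 6 arrays differed by at most 0.0049, so the arrays had already been brought to 1 common distribution. That leaves differences in total RNA or overall signal between arrays out of reach, and control probe sets went through the same step. The array design's probe file and genome build are not given in the sources used here, so no coordinates are reported.

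The design had allowed for either log2 or linear values, and log2 was taken of the deposited intensity with no pseudocount, since all values were above 0. The table held 54675 probe sets, of which 62 Affymetrix controls were left out of the tests and 54613 were tested. Of these, 41091 were paired with 1 gene in the platform annotation, 1801 with several genes and 11721 with none listed there. Gene symbols were compared with a RefSeq table through the gene identifier, which left 54 single-gene probe sets without a match and updated 0 symbols. A gene was represented by the single-gene probe set with the highest mean over all 6 arrays, which gave 19775 genes, 10523 of them with over 1 probe set. Among 1864 genes with over 1 changed probe set, 121 had probe sets that changed in opposite directions.

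Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 6 arrays, without covariates, 2-sided, with Benjamini-Hochberg adjustment over probe sets or over genes and a threshold of 0.05. Gene lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 38 lists, with an estimated correlation and the fry test beside it. With an estimated correlation, camera takes p from the few residual degrees of freedom of the 6 arrays, and from fewer with a block. The preset uses many more, so passing is harder for every list with an estimated correlation. The lists covered androgen-induced and androgen-repressed genes, androgen receptor coregulators, DNA replication, mitosis, cell cycle inhibitors and D-type cyclins, p53 targets, pro- and anti-apoptotic genes, interferon-stimulated, NF-kB, MYC and ribosome biogenesis genes. They also covered ER chaperones, ATF4 targets, cholesterol and fatty acid synthesis, hypoxia, heat shock, NRF2, immediate early, MAPK and WNT genes, epithelial junctions, mesenchymal transition, 8q24 genes, RNA interference, ribosomal proteins, oxidative phosphorylation, the proteasome, autophagy, histones, polyamines and splicing. List members with no single-gene probe set in the annotation used were not analysed here. Markers of luminal, basal, neuroendocrine, fibroblast and smooth muscle, and immune and endothelial cells were included. The members of all lists were chosen from general knowledge, with no published set named as their source. The lists, the design, the rule for named genes and most of the other settings were fixed before the data were examined. Array quality measures were compared with 2-sided exact permutation tests in SciPy 1.17.1 under Python 3.11.15, for which 3 against 3 arrays give no p below 0.1. Figures were drawn with matplotlib 3.10.9.

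Genes were named by rule: the 12 largest rises and the 12 largest falls among genes that passed with no overlap between groups and had an informative symbol, and up to 4 members with the smallest p from each shifted list and from the androgen-induced, androgen-repressed and 8q24 lists. In shifted lists these were taken in the list's direction, and up to 2 members were named from each list that was not shifted. Genes named outside this rule are marked as chosen after their values were seen.

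Both groups carry replicate numbers 1 to 3 in the labels. Deviations from the group means correlated across probe sets at 0.47, 0.30 and 0.34 for arrays with the same number, all above 0.1, so the numbers were treated as pairing the arrays, from the data and not from a stated shared day or batch. Arrays 2 and 3 were linked across groups as well (0.37 and 0.24), while array 1 deviated in the opposite direction from arrays 2 and 3 (-0.31 to -0.44), so the pairing lay mainly between array 1 and the others. Deviations from a group mean cancel within the group, so these values do not tell whether numbers 2 and 3 pair arrays. The main fit left this pairing out, and the replicate number as a block was an alternative.

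Other settings fixed in advance were the replicate block, leaving out probe sets or genes below the median level, a further quantile normalization, a shift to a common median, an intensity trend with a robust prior, ordinary variance, each array left out in turn, the mean of all probe sets of a gene, leaving out probe sets named _x_at or _s_at (which can match several transcripts or genes), a fold change of at least 1.5, and camera with an estimated correlation or fry. Added after seeing the data were arrays 2 and 3 alone, the array set (1 against 2 and 3) as a block, arrays 2 and 3 averaged as 1 replicate with and without that block, the ACTB 3' to 5' difference as a covariate, and an estimated correlation with the replicate block. The procedure was tested on simulated data drawn for these 19775 genes. It recovered 43.3% of 67 genes changed by 0.5 on the log2 scale and 100% of 66 genes each at 1 and at 2, and 12 of 203 calls (5.9%) were false. The mitosis list was also shifted by -0.7 there. Its called members counted as true among the 203 calls, which lowers the false share. Arrays and genes were drawn independently, unlike the closely alike arrays 2 and 3 of the data, so these shares need not hold for the real arrays.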

Results

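Total RNA from LNCaP cells, an androgen-responsive human prostate cancer line, was measured on 6 single-colour Affymetrix arrays. The cells had been treated with small interfering RNA (siRNA) to PCARNEQ, a non-coding RNA, or with control siRNA to EGFP, a fluorescent protein that human cells lack. Each group had 3 arrays, named here siPCARNEQ arrays 1 to 3 and siEGFP arrays 1 to 3. The median intensity was 130.8 on every array and the range was 7.35 to 42200, and the number of arrays limited the precision. The labels describe a triplicate and name no separate cultures, so p-values measured only the spread between these arrays, which may be technical.

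The comparison asked which transcripts differ when PCARNEQ is targeted. Genes of DNA replication, mitosis and ribosome biogenesis fell in siPCARNEQ cells, while androgen-induced genes, luminal prostate markers and epithelial junction genes rose as lists, in the camera test with a preset correlation. Of these lists, only ribosome biogenesis passed with an estimated correlation (adjusted p = 0.0328, and 0.266 with the replicate number as a block as well), against adjusted p = 0.359 for DNA replication, 0.762 for mitosis, 0.114 for androgen-induced genes, 0.114 for luminal markers and 0.359 for junction genes. The estimated correlation was 0.409 for DNA replication, 0.865 for mitosis and 0.094 for junction genes. It was -0.012 for androgen-induced genes and -0.057 for luminal markers, below the preset 0.01, so a higher correlation does not explain their loss. The test with an estimated correlation rests on few residual degrees of freedom, so not passing it does not show that a list was unshifted. The median log2 change was -0.91 for mitosis genes, -0.68 for DNA replication genes, -0.56 for ribosome biogenesis genes, 0.45 for androgen-induced genes and 0.53 for luminal markers (n = 3 arrays per group). Single genes moved further: MBNL3, a muscleblind RNA-binding protein, fell by 3.32 on the log2 scale (SE 0.11), and S1PR3, a receptor for sphingosine-1-phosphate, rose by 3.08 (SE 0.44). Of 19775 genes, each represented by 1 probe set, 3007 rose and 2438 fell with limma at a Benjamini-Hochberg adjusted p below 0.05. At least a 2-fold change was reached by 420 genes that rose and 424 that fell, and at least a 4-fold change by 37 and 53. Among all 54613 probe sets tested, 5420 rose and 4702 fell, 10122 in all, against 5829 without siEGFP array 2 and 5870 without siEGFP array 3.

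The level of the targeted RNA was not analysed here, because no probe set was paired with PCARNEQ, or with PRNCR1, a possible later name known from general knowledge. Arrays 2 and 3 of a group resembled each other closely, and array 1 stood apart in both groups. Across probe sets, the SD of the log2 difference between arrays 2 and 3 was 0.136 in siPCARNEQ and 0.129 in siEGFP, against 0.371 to 0.373 and 0.232 to 0.239 for array 1 against the others. The log2 difference between the 3' and 5' control probe sets of ACTB, a measure of RNA integrity, was 1.84 in siPCARNEQ array 1 and 0.63 to 0.78 in the other 5 arrays. Group means of this difference were 1.07 ± 0.67 for siPCARNEQ and 0.69 ± 0.08 for siEGFP (SD, n = 3), with a 2-sided exact permutation p of 0.5, where 0.1 is the smallest p that 3 against 3 arrays allow. Counted with arrays 2 and 3 of each group averaged as 1 replicate, 2236 genes changed, all of them among the 5445, and 5165 changed when the array set (1 against 2 and 3) was a block as well. Of the 5445, 4524 were among these 5165. Averaging with that block leaves very little spread to measure, so its calls, here and below, rest mostly on variance that eBayes shares across genes. Arrays 2 and 3 alone gave 8229.

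**Figure D1:**
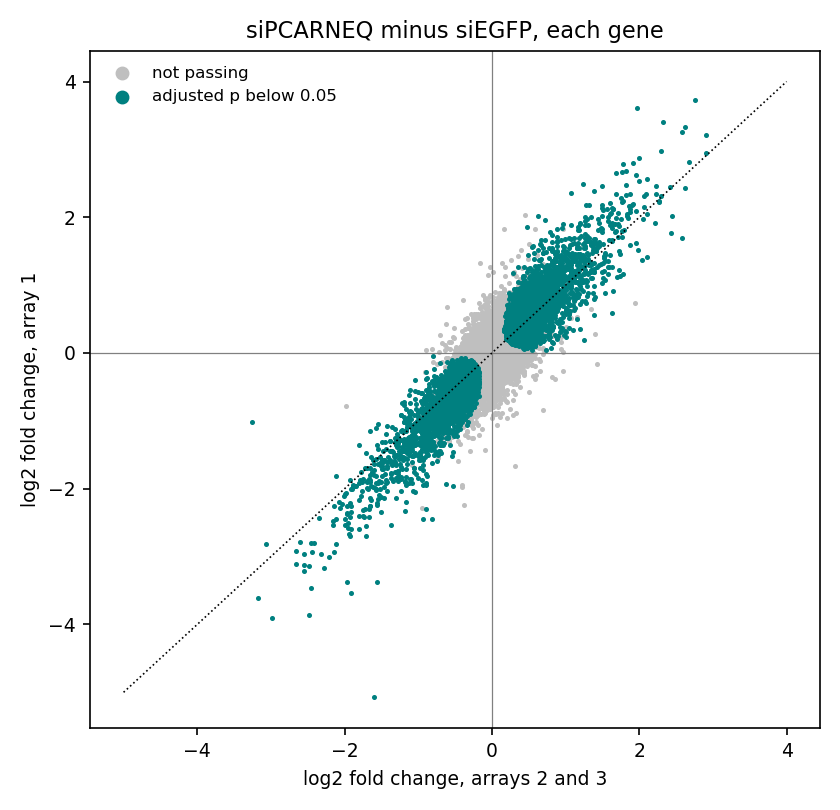
Each point is 1 of the 19775 genes, with its log2 fold change (siPCARNEQ minus siEGFP) between the 2 arrays numbered 1 on the vertical axis and between the means of arrays 2 and 3 on the horizontal axis, teal where the adjusted p over all 6 arrays was below 0.05. Across all genes, which are not independent replicates, the changes correlated with r = 0.86, and the teal genes were chosen over the same 6 arrays that both axes show.

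Most genes called in arrays 2 and 3 alone had the same direction in array 1, which had no part in the call. Of the 8229 such genes, 7567 (92%) had the same sign in array 1, where unrelated signs would give 49.8%. In 8692 of the 19775 genes (44%) the groups did not overlap, where chance gives 10% for 6 exchangeable arrays and 33.3% if arrays 2 and 3 of a group were exact repeats. Changes had a wider spread between the single arrays 1 (SD 0.52 across genes) than between the means of arrays 2 and 3 (SD 0.42), and the median change of all genes was -0.014.

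Among the 12 genes with the largest rise were S1PR3 (probe set 228176_at, adjusted p = 0.00204) and DIO1, a deiodinase that activates thyroid hormone (206457_s_at, adjusted p = 2.51e-05). DIO1 lay at 9.04 ± 0.07 in siPCARNEQ and 6.03 ± 0.12 in siEGFP (log2 intensity, SD, n = 3), with no overlap between arrays. In 9 of the 24 genes with the largest changes, DIO1, STON1, KRT19, THRSP, SERPIND1, MSMB, NXT2, E2F7 and GNAI1, the lower group lay below the array median of 7.03, where a level was not shown to be above background and the size of the change is uncertain. THRSP, a thyroid hormone responsive regulator of lipid synthesis, rose by 2.72 (SE 0.35). KRT19, a keratin of simple epithelia, rose by 2.80 (SE 0.20), and MSMB, a protein secreted by luminal prostate cells, by 2.52 (SE 0.18). AQP3, a channel for water and glycerol, rose by 2.43 and the interleukin receptor subunit IL6R by 2.31. ARL15, STON1 and SERPIND1 rose by 2.92, 2.85 and 2.56. The secreted phospholipase PLA2G2A and the semaphorin SEMA3C rose by 2.68 and 2.52 with wide errors (SE 0.62 and 0.67, adjusted p = 0.0163 and 0.029), and neither passed with arrays 2 and 3 averaged (adjusted p = 0.0748 and 0.0973). PLA2G2A and SEMA3C did not pass without siPCARNEQ array 2 (adjusted p = 0.0509 and 0.0809) or array 3 (0.0536 and 0.0822) either, and SEMA3C rose by 1.67 without siEGFP array 1. Averaged over all probe sets of the gene, SEMA3C did not pass (2.08, adjusted p = 0.0527), and KRT19, AQP3, STON1 and THRSP rose by 1.40, 1.15, 1.51 and 1.77.

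Among the 12 genes with the largest fall, MBNL3 (229498_at) went from 10.47 ± 0.03 in siEGFP to 7.15 ± 0.22 in siPCARNEQ, and NXT2, an mRNA export factor, fell by 3.29 (SE 0.30). E2F7, a repressor of the E2F family that acts in the cell cycle, fell by 2.98 (SE 0.09, adjusted p = 2.51e-05). GNAI1, an inhibitory G protein subunit, fell by 2.94 (SE 0.31). DTD2, QSER1, PAQR3, TMTC3, SMIM13, REEP3 and EMB fell too, with log2 changes of -2.81, -2.79, -2.77, -2.74, -2.74, -2.68 and -2.67 and adjusted p of 0.00026 or less. RNA45SN5, a ribosomal RNA precursor encoded in many near-identical copies, fell by 2.76 (SE 0.64) and is uncertain, with a change of -5.07 in array 1, -1.60 in arrays 2 and 3, and an adjusted p of 0.0561 with arrays 2 and 3 averaged. Averaged over all probe sets of the gene, MBNL3, E2F7, QSER1, PAQR3 and SMIM13 had smaller falls, with log2 changes of -1.60, -1.78, -1.67, -1.43 and -1.74.

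**Figure D2:**
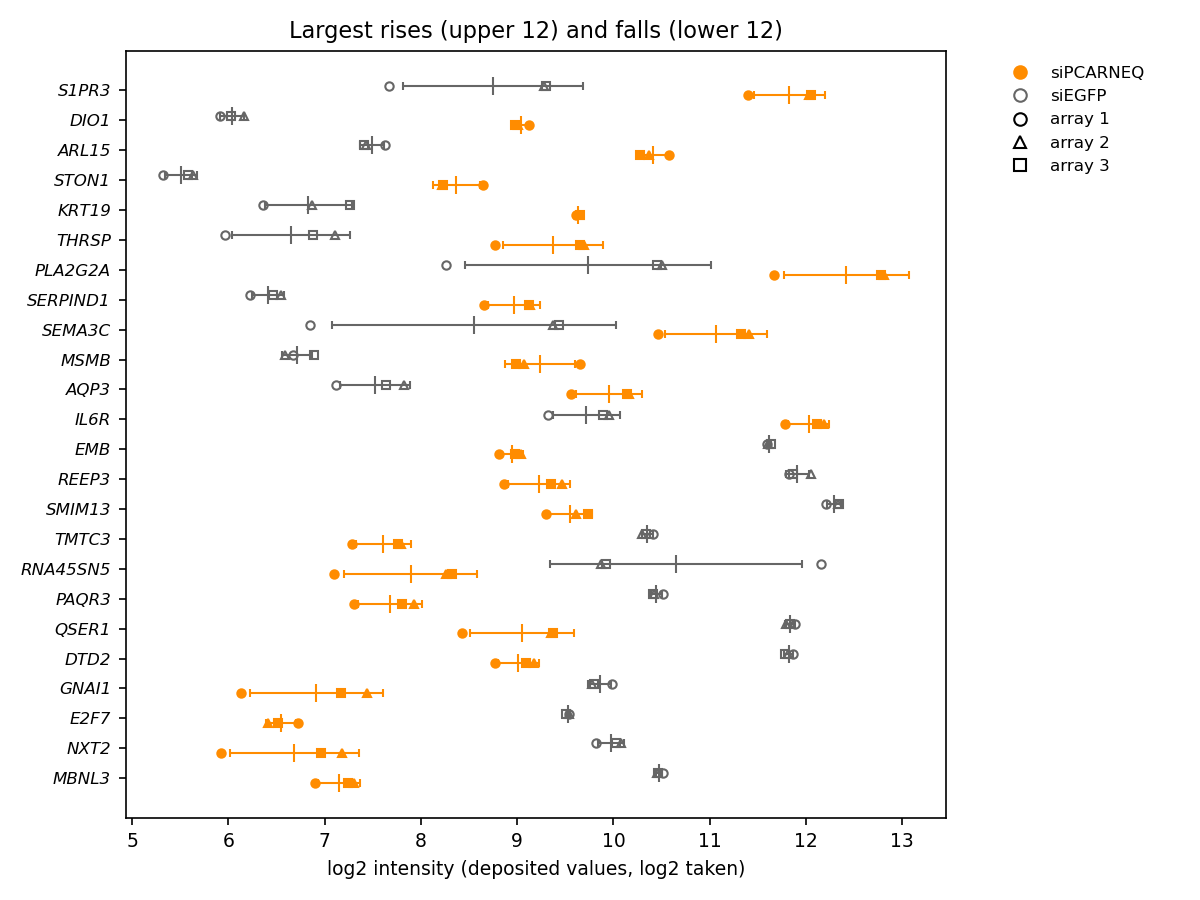
Log2 intensity on each of the 6 arrays (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall, with siPCARNEQ arrays filled and orange, siEGFP arrays open and grey, vertical ticks at group means and bars of 1 SD (n = 3). The siPCARNEQ and siEGFP arrays do not overlap for any of these 24 genes, and the siEGFP values of SEMA3C and RNA45SN5 spread most between array 1 and arrays 2 and 3.

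DNA replication and G1/S genes fell together. Of 52 measured members, 42 fell, 0 rose and 10 did not pass (45 fell and 0 rose adjusted over the list alone, and 0 rose at an unadjusted p below 0.05 with limma). GINS1, a subunit of the replicative helicase complex, fell by 2.04 (SE 0.07, adjusted p = 2.51e-05), and MCM6, a subunit of the MCM helicase, by 1.79 (SE 0.15). RFC3, part of the clamp loader, and ORC6, part of the origin recognition complex, fell by 1.13 and 0.80. The median change was -0.66 in array 1 and -0.72 in arrays 2 and 3. The limma camera test with a preset correlation gave an adjusted p of 1.69e-16 over 38 lists, and adjusted p = 0.359 with an estimated correlation. With arrays 2 and 3 averaged, 18 members fell, and 43 when the array set was a block as well.

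Mitosis and G2/M genes fell as well, with 43 of 51 members lower, 0 higher and 8 not passing (49 fell and 0 rose adjusted over the list alone, and 0 rose at an unadjusted p below 0.05 with limma). BUB1B, a spindle checkpoint kinase, fell by 1.25 (SE 0.13, adjusted p = 0.000618), and CDCA8, a subunit of the chromosomal passenger complex, by 1.20. The condensin subunits NCAPG and NCAPH fell by 1.14 and 1.05. The median was -1.08 in array 1 and -0.77 in arrays 2 and 3. Camera gave an adjusted p of 2e-15, and adjusted p = 0.762 with an estimated correlation, which was 0.865 between the members of this list. With arrays 2 and 3 averaged, 17 members fell, and 48 when the array set was a block as well. Without siEGFP array 2 or array 3, 24 members fell.

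MYC targets and ribosome biogenesis genes fell in 26 of 33 members, with 0 higher and 7 not passing (30 fell and 0 rose adjusted over the list alone, and 0 rose at an unadjusted p below 0.05 with limma). DDX21, a nucleolar helicase, fell by 1.24 (SE 0.07, adjusted p = 7.2e-05), and POLR1B, a subunit of RNA polymerase I, by 1.14 (SE 0.07). NOP16, a nucleolar protein, fell by 1.06 and CAD, an enzyme of pyrimidine synthesis, by 0.89. The median was -0.59 in array 1 and -0.53 in arrays 2 and 3. Camera gave an adjusted p of 9.09e-14. This was the 1 list that also passed with an estimated correlation, at adjusted p = 0.0328, and it did not pass with an estimated correlation and the replicate number as a block, at adjusted p = 0.266. With arrays 2 and 3 averaged, 17 members fell, and 26 when the array set was a block as well.

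Androgen-induced genes rose as a list, with members moving both ways. Of 42 members, 20 rose, 5 fell and 17 did not pass (23 rose and 6 fell adjusted over the list alone), and 8 of the 42 belong to other lists as well. MAF, a transcription factor, rose by 1.51 (SE 0.09, adjusted p = 7.2e-05), and NDRG1, a stress-responsive protein, by 1.42 (SE 0.07, adjusted p = 3.99e-05). ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, rose by 1.27 and the glycine methyltransferase GNMT by 1.22. The 5 members that fell, named after their values were seen, were PTGER4 (-1.39), STEAP4 (-0.98), NCAPD3 (-0.88), TPD52 (-0.83) and CENPN (-0.75). NCAPD3 is a condensin subunit and CENPN a centromere protein, and STEAP4 lay at 6.63 in siPCARNEQ, below the array median of 7.03. FKBP5 and KLK2, singled out likewise as widely used androgen targets, had changes of 0.07 (SE 0.11, adjusted p = 0.694) and 0.46 (SE 0.21, adjusted p = 0.152) in their brightest probe sets, while 1 of the other 3 probe sets of KLK2 rose by 0.99 (adjusted p = 0.00221 over probe sets). The median was 0.50 in array 1 and 0.37 in arrays 2 and 3. Camera gave an adjusted p of 7.14e-05, and adjusted p = 0.114 with an estimated correlation. With arrays 2 and 3 averaged, 14 members rose and 2 fell, against 21 and 5 when the array set was a block as well.

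Luminal prostate markers rose in 9 of 13 members, with 0 lower and 4 not passing (9 rose and 0 fell adjusted over the list alone, and 0 fell at an unadjusted p below 0.05 with limma), and 8 of the 13 are shared with other lists. Besides MSMB, ACP3, which encodes prostatic acid phosphatase, rose by 1.59 (SE 0.18, adjusted p = 0.000751), and TMPRSS2, an androgen-regulated serine protease, by 1.16 (SE 0.13). KLK3, which encodes prostate-specific antigen, rose by 0.51 (SE 0.07, adjusted p = 0.00144). The median was 0.60 in array 1 and 0.55 in arrays 2 and 3. Camera gave an adjusted p of 0.000108, and adjusted p = 0.114 with an estimated correlation.

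Epithelial junction genes rose in 12 of 22 members, while 2 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone). Besides KRT19, the tight junction protein CGN rose by 1.82 (SE 0.11, adjusted p = 7.2e-05), the epithelial transcription factor ELF3 by 0.87 and the claudin CLDN4 by 0.50. The 2 members that fell, named after their values were seen, were EPCAM (-0.40), an epithelial adhesion molecule, and OCLN (-0.50), which encodes occludin. The median was 0.36 in array 1 and 0.32 in arrays 2 and 3. Camera gave an adjusted p of 0.000814, and adjusted p = 0.359 with an estimated correlation. With arrays 2 and 3 averaged, 4 members rose and 0 fell, against 12 and 2 when the array set was a block as well. Without siEGFP array 2 or array 3, 7 members rose and 2 fell.

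ER chaperones and ER-associated degradation genes rose in 9 of 24 members, with 0 lower and 15 not passing (9 rose and 0 fell adjusted over the list alone, and 1 fell at an unadjusted p below 0.05 with limma). The members that rose included the stress sensors ATF6 (0.82, SE 0.07, adjusted p = 0.000277) and ERN1 (0.74), the degradation factor EDEM1 (0.87) and the co-chaperone DNAJC3 (0.60). HSPA5, a widely used marker of ER stress singled out after its value was seen, had a change of 0.12 (SE 0.08, adjusted p = 0.314) in its brightest probe set and rose by 0.84 in its other one (adjusted p = 0.00636 over probe sets). The list median was 0.17 in array 1 and 0.18 in arrays 2 and 3. Camera gave an adjusted p of 0.000814, and adjusted p = 0.114 with an estimated correlation. With arrays 2 and 3 alone, 15 members rose and 1 fell, and without siEGFP array 1, 7 rose and 1 fell. With arrays 2 and 3 averaged, 6 rose and 0 fell, against 7 and 1 when the array set was a block as well.

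Splicing factors, replication-dependent histone genes and p53 target genes fell as lists too, in camera with a preset correlation. None of them passed with an estimated correlation (adjusted p = 0.114, 0.195 and 0.771). Of 30 splicing factors, 11 fell, 1 rose and 18 did not pass (14 fell and 3 rose adjusted over the list alone), with SF3B3 at -0.42 and HNRNPU at -0.37. The member that rose, named after its value was seen, was SRSF5 (0.26, adjusted p = 0.0346). The list median was -0.25 (-0.29 in array 1 and -0.20 in arrays 2 and 3), with a camera adjusted p of 0.00152, and adjusted p = 0.114 with an estimated correlation. With the replicate number as a block 16 members fell and 3 rose, and with arrays 2 and 3 averaged 1 fell, or 9 when the array set was a block as well. Without siEGFP array 2, 6 members fell, and 7 without siEGFP array 3. SF3B3, HNRNPU and SRSF3 did not pass with arrays 2 and 3 averaged (adjusted p = 0.0601, 0.0818 and 0.0701), and HNRNPU fell by 1.45 without probe sets that can match several transcripts. SRSF10 and SRSF3 fell by 0.79 and 0.41 in their brightest probe sets but had changes of 0.09 and 0.01 when probe sets that can match several transcripts were left out, where the list no longer passed (median -0.11, adjusted p = 0.0898).

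Of 14 histone genes, 7 fell, 0 rose and 7 did not pass (8 fell and 1 rose adjusted over the list alone, and 1 rose at an unadjusted p below 0.05 with limma). H3C2 fell by 1.67 (SE 0.24, adjusted p = 0.00216), H2BC4 by 0.56, H1-3 by 0.47 and H1-5 by 0.41, and H1-5 did not pass without siPCARNEQ array 3 or siEGFP array 2 (adjusted p = 0.0529 and 0.0596). Histone genes are near-identical in sequence, so single members are uncertain. H1-5 in both groups and H3C2 in siPCARNEQ (6.19) lay below the array median of 7.03, where a level was not shown to be above background. The list median was -0.29 (-0.40 in array 1 and -0.25 in arrays 2 and 3), with a camera adjusted p of 0.00885, and adjusted p = 0.195 with an estimated correlation. Without the genes below the median level the list did not pass (median -0.22, adjusted p = 0.224), and with arrays 2 and 3 averaged 1 member fell, or 6 when the array set was a block as well. Without siEGFP array 2, 3 members fell, and 4 without siEGFP array 3 or siPCARNEQ array 2. H1-3, H2BC4 and H1-5 did not pass with arrays 2 and 3 averaged (adjusted p = 0.0699, 0.0631 and 0.0958).

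Of 23 p53 target genes, 9 fell, 2 rose and 12 did not pass (12 fell and 2 rose adjusted over the list alone). ZMAT3, an RNA-binding zinc finger protein, fell by 2.54 (SE 0.13, adjusted p = 5.03e-05), and the death receptor FAS by 1.17 (SE 0.14), though FAS had a change of -0.24 without probe sets that can match several transcripts. CCNG1 and TRIAP1 each fell by 0.71. The 2 that rose, named after their values were seen, were GADD45A (0.52), a growth arrest and DNA damage gene, and SESN1 (0.41), a sestrin, and CDKN1A, which encodes the cell cycle inhibitor p21, had a change of 0.21 (adjusted p = 0.0974). The list median was -0.28 (-0.39 in array 1 and -0.24 in arrays 2 and 3), with a camera adjusted p of 0.0263, and adjusted p = 0.771 with an estimated correlation. This list did not pass without siEGFP array 1 (median -0.25, adjusted p = 0.109) or in arrays 2 and 3 alone (adjusted p = 0.0543), and its adjusted p in camera ran from 0.00989 to 0.805 over 19 alternatives. The number that fell was 5 with arrays 2 and 3 averaged and 11 when the array set was a block as well.

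**Figure D3:**
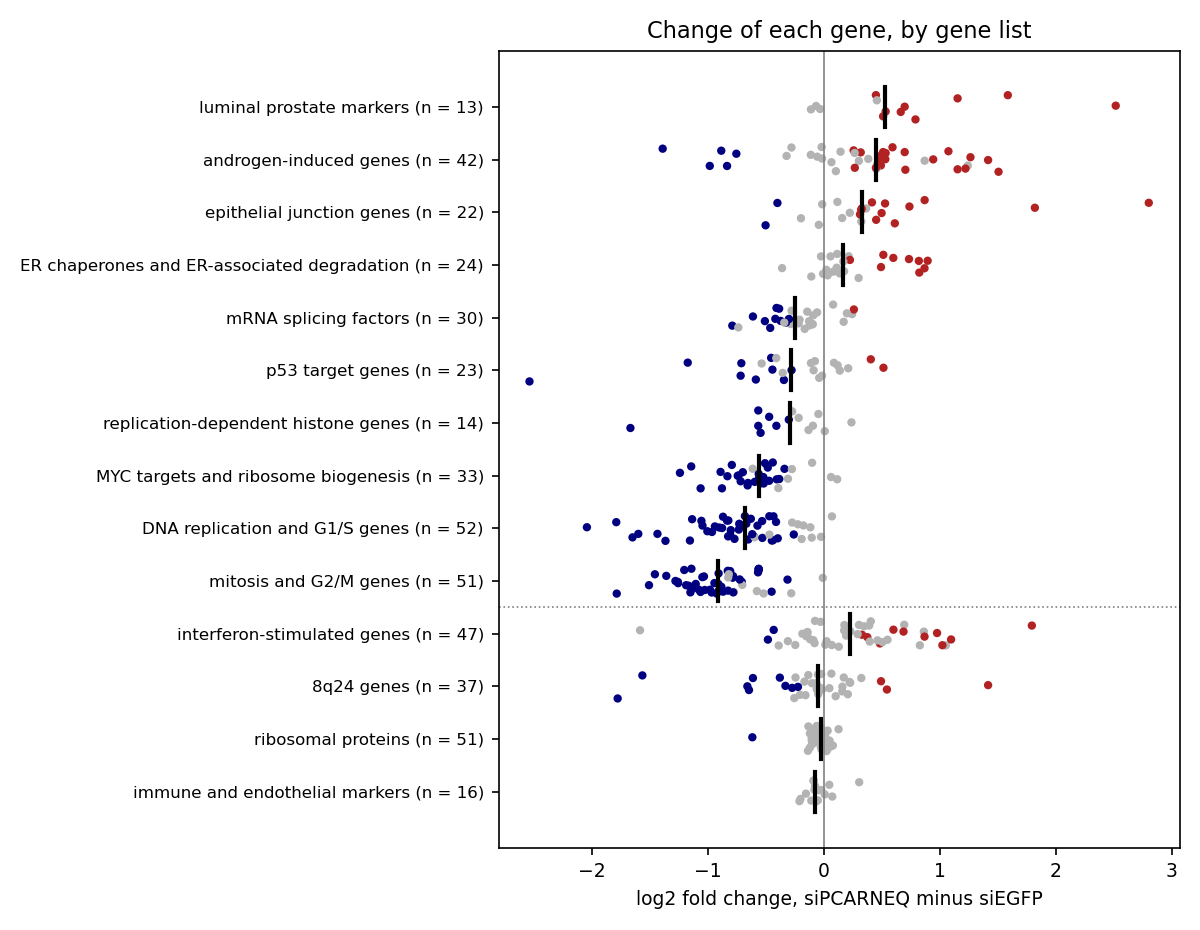
Log2 fold change of every measured gene (points, horizontal axis, siPCARNEQ minus siEGFP) in the 10 lists that passed the camera test, above the dotted line, and in 4 that did not, with red for genes that rose, blue for genes that fell, grey for genes that did not pass and a black bar at the list median. Medians run from 0.53 for luminal markers to -0.91 for mitosis genes, and lie at -0.02 for ribosomal proteins and -0.07 for immune and endothelial markers.

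Genes around the 8q24 region, to which an array label ties the siRNA, were not shifted as a list (37 members, median -0.05, camera adjusted p = 0.575). Of these, 9 fell and 3 rose (9 and 4 adjusted over the list alone). The counts were 10 and 6 with the replicate number as a block, 9 and 8 with arrays 2 and 3 alone, 3 and 3 with arrays 2 and 3 averaged, 7 and 4 when the array set was a block as well, and 5 and 3 without siEGFP array 3. TMEM65 fell by 1.77 (SE 0.19) and FAM91A1 by 0.61, while NDRG1 and NSMCE2 rose, the latter by 0.55. MYC, the growth-promoting transcription factor in this region, fell by 1.56 (SE 0.24, adjusted p = 0.00274), with a change of -2.33 in array 1 and -1.18 in arrays 2 and 3. PVT1, a non-coding neighbour of MYC singled out after its value was seen, fell by 0.33 (SE 0.08, adjusted p = 0.016). PVT1 lay at 6.67 in siEGFP and 6.34 in siPCARNEQ, below the array median of 7.03, so its level was not shown to be above background. FAM91A1 had a change of -0.24 and did not pass when probe sets that can match several transcripts were left out.

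Androgen-repressed genes moved both ways (10 members, 2 rose and 3 fell, as adjusted over the list alone, median -0.04, camera adjusted p = 0.831). CAMK2N1, an inhibitor of a calmodulin-dependent kinase, rose by 1.72 (SE 0.22) and the chemokine receptor ACKR3 by 0.67, though ACKR3 had a change of 0.36 and did not pass when averaged over its probe sets (adjusted p = 0.0613). SERPINI1 fell by 1.78 (SE 0.19), and UGT2B15, an enzyme that inactivates androgens, by 1.45 (SE 0.27), where near-identical family members can share probes. Among 17 androgen receptor coregulators, 5 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.378), with NCOA2 at 0.74 and KDM1A at -0.60. The median was -0.03 without siPCARNEQ array 1, where 6 rose and 4 fell, and 0.29 without siPCARNEQ array 2.

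Interferon-stimulated genes did not pass over all arrays (47 members, 10 rose and 2 fell, as adjusted over the list alone, median 0.23, camera adjusted p = 0.0667). With the replicate number as a block the list passed (adjusted p = 0.00466, 22 rose and 4 fell), but not with an estimated correlation and that block (adjusted p = 0.324). It passed with arrays 2 and 3 averaged and the array set as a block (adjusted p = 0.00311, 18 rose and 3 fell). It did not pass with arrays 2 and 3 averaged without the array set as a block (adjusted p = 0.0704, 2 rose and 1 fell). It passed without siPCARNEQ array 1 (median 0.40, adjusted p = 0.000759) and without siEGFP array 2 or 3 (medians 0.33 and 0.36, adjusted p = 0.0144 and 0.00669), and the median was 0.14 without siPCARNEQ array 2, 0.11 without siPCARNEQ array 3 and 0.02 without siEGFP array 1. The number that rose was 5 or 6 with 1 array other than siPCARNEQ array 1 left out. Its adjusted p in camera ran from 0.000372 to 0.883 over 19 alternatives, the highest being adjusted p = 0.883 with an estimated correlation. TRIM22 rose by 1.79 (SE 0.07, adjusted p = 2.51e-05) and LGALS3BP by 0.98. In siEGFP, TRIM22 lay at 6.92, just below the array median of 7.03. IFIT1, a widely used member singled out after its value was seen, had a change of 0.19 with an SE of 0.88. Genes of the RNA interference machinery did not pass camera (12 members, 1 rose and 3 fell, or 1 and 6 adjusted over the list alone, median -0.19, adjusted p = 0.0935, and 0.0472 without siPCARNEQ array 1), with AGO4 at 1.20 (SE 0.06) and TNRC6A at -0.92 (SE 0.08). The list passed fry, downward (adjusted p = 7.48e-05). With the replicate number as a block, and also without siPCARNEQ array 1, 6 of the RNA interference genes fell and 1 rose. With arrays 2 and 3 averaged and the array set as a block, 3 fell and 1 rose. Autophagy and lysosome genes did not pass over all arrays (22 members, 10 rose and 3 fell, or 12 and 3 adjusted over the list alone, median 0.31, adjusted p = 0.127), with WIPI1 at 1.44 and the sialidase NEU1 at 0.92, and with arrays 2 and 3 averaged 3 of them rose and 1 fell, or 9 and 3 when the array set was a block as well. This list passed with the mean of all probe sets of a gene (adjusted p = 0.043) and without probe sets that can match several transcripts (adjusted p = 0.0131). It did not pass with an estimated correlation (adjusted p = 0.771, and 0.91 with the replicate block). Of its members, 6 rose and 1 fell without siEGFP array 2, 7 and 1 without siEGFP array 3, and 9 and 1 without siEGFP array 1.

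Markers of other cell types were not shifted. Of 16 immune and endothelial markers, 0 changed with limma, adjusted over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05 (CD3D, -0.21, adjusted p = 0.107, and 0.0489 without siPCARNEQ array 3). CD74 had a change of -0.20. Of 10 basal epithelial markers, KRT14 rose by 1.02 and ITGA6 fell by 0.98 (adjusted p = 0.771 for the list). KRT14 lay at 5.28 in siEGFP and 6.3 in siPCARNEQ, below the array median of 7.03, where a level was not shown to be above background. In this paragraph SYT1, LOX, TGFB2 and CD3D also lay below it in both groups, and LUM did in siEGFP (5.78). Of 13 neuroendocrine markers, SYT1 and ENO2 rose by 0.70 and 0.72 (adjusted p = 0.914 for the list), ENO2 not passing without siEGFP array 2 or 3 (adjusted p = 0.114 and 0.104) or with arrays 2 and 3 averaged (0.117). Of 14 fibroblast and smooth muscle markers, 2 rose and 1 fell (adjusted p = 0.906), with COL1A1 at 1.11, and LUM at 1.39 in its brightest probe set and -0.06 without probe sets that can match several transcripts. That list had a mean of 0.11, a median of -0.08 and a camera direction of down. Among 17 mesenchymal transition genes, LOX fell by 0.88 and TGFB2 by 0.76, and neither passed with arrays 2 and 3 averaged (list adjusted p = 0.933). TGFB2 had a change of -0.28 and did not pass when averaged over its probe sets (adjusted p = 0.0587). LOX did not pass without siEGFP array 2 or 3 (adjusted p = 0.0811 and 0.0799), nor TGFB2 without siPCARNEQ array 1 or 2 or siEGFP array 2 or 3 (0.0575, 0.061, 0.0991 and 0.0971). Adjusted over the list alone, 0 mesenchymal genes rose or fell with limma (2 and 3 at an unadjusted p below 0.05), 1 neuroendocrine gene rose, and the counts of the basal and fibroblast lists stayed as given. With the replicate number as a block, 1 mesenchymal gene rose and 3 fell, 2 neuroendocrine genes rose and 2 fell, and 3 fibroblast genes rose and 2 fell. With arrays 2 and 3 averaged and the array set as a block, these were 1 and 2, 2 and 0, and 2 and 2. Without siEGFP array 2 or 3, 0 mesenchymal genes rose or fell with limma, 1 fell without siPCARNEQ array 2, and 1 rose and 2 fell without siPCARNEQ array 1 or siEGFP array 1. Fibroblast genes that fell numbered 2 without siPCARNEQ array 3 or siEGFP array 2, and 1 immune or endothelial marker rose without siPCARNEQ array 1.

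Stress and growth lists held genes that rose and genes that fell, except for MAPK output genes, where over all arrays the genes that passed had fallen. Hypoxia and glycolysis genes counted 9 that rose, with ANKRD37 at 0.92, and 8 that fell among 28 (adjusted p = 0.771). BCL2L11 fell by 1.29 and BIK rose by 1.29 among 22 pro-apoptotic genes (5 rose, 6 fell, adjusted p = 0.857), and BCL2L1 and BIRC2 rose by 0.60 and 0.33 among 9 anti-apoptotic genes (2 rose, 2 fell, adjusted p = 0.826). BCL2L1 had a change of 0.39 and did not pass when averaged over its probe sets (adjusted p = 0.142), and BIRC2 did not pass with arrays 2 and 3 averaged (adjusted p = 0.134, and 0.0693 with the array set as a block). CDKN1C, a cell cycle inhibitor, rose by 1.72 and RBL2 by 0.79 among 14 cell cycle inhibitors and D-type cyclins (2 rose, 2 fell, adjusted p = 0.771). HMOX1, the stress-induced haem oxygenase, rose by 1.64 and SLC7A11 fell by 0.62 among 17 NRF2 genes (1 rose, 4 fell, adjusted p = 0.556). Among 11 heat shock genes 2 rose and 5 fell (adjusted p = 0.181), with HSPD1 at -0.44 (adjusted p = 0.051 with arrays 2 and 3 averaged), and with HSPA4 at -0.77 in its brightest probe set but 0.46 without probe sets that can match several transcripts. DDIT3 and JDP2 rose by 0.67 and 0.89 among 39 ATF4 targets (4 rose, 5 fell, adjusted p = 0.826), and KLF6 rose by 0.66 among 20 immediate early genes (5 rose, 1 fell, adjusted p = 0.575). LIF and NFKB2 fell by 0.59 and 0.40 among 21 NF-kB genes (1 rose, 2 fell, adjusted p = 0.826). NFKB2 did not pass when averaged over its probe sets (-0.21, adjusted p = 0.0506), without probe sets that can match several transcripts (-0.26, adjusted p = 0.235) or with arrays 2 and 3 averaged (adjusted p = 0.0959). SPRY1 fell 2.82-fold and SPRED1 2.27-fold among 17 MAPK output genes (0 rose, 4 fell, adjusted p = 0.503, with 1 higher at an unadjusted p below 0.05 with limma), and 1 of these rose with the replicate number as a block and 2 without siPCARNEQ array 1. GSK3B fell by 0.97 and WNT5A rose by 0.79 among 15 WNT genes (4 rose, 1 fell, adjusted p = 0.857). Adjusted over the list alone, 11 hypoxia genes rose and 9 fell, 6 pro-apoptotic genes rose and 6 fell, 2 cell cycle inhibitors and cyclins rose and 3 fell, 3 NRF2 genes rose and 6 fell, and 3 heat shock genes rose and 6 fell, with the other counts of these lists as given. With the replicate number as a block, 3 cell cycle inhibitors and cyclins rose and 4 fell, 4 anti-apoptotic genes rose and 2 fell, and 6 ATF4 targets rose and 9 fell. With arrays 2 and 3 averaged and the array set as a block, these were 3 and 2, 1 and 2, and 5 and 6. Averaging arrays 2 and 3 left 5 hypoxia genes that rose and 3 that fell, 2 and 5 pro-apoptotic genes, and 1 and 1 immediate early genes, against 8 and 7, 4 and 5, and 7 and 2 when the array set was a block as well. It left 0 heat shock genes that rose and 1 that fell, 2 and 1 ATF4 targets, 1 and 1 WNT genes, 1 and 2 NRF2 genes and 0 and 2 MAPK genes. With the array set as a block as well, these were 0 and 5, 5 and 6, 3 and 2, 1 and 2, and 1 and 4. Leaving out 1 array moved several of these counts by over 1.5 times. Immediate early genes that rose numbered 2 without siPCARNEQ array 3 and 3 without siPCARNEQ array 2 or siEGFP array 2 or 3, and 2 fell without siPCARNEQ array 1. Pro-apoptotic genes that rose numbered 3 without siPCARNEQ array 3 or siEGFP array 1 or 3. Of the anti-apoptotic genes, 4 rose and 3 fell without siPCARNEQ array 1, 1 fell without siPCARNEQ array 2 or 3 or siEGFP array 1, and 0 fell without siEGFP array 2 or 3. Hypoxia genes that rose and fell numbered 8 and 5 without siPCARNEQ array 2, 7 and 5 without siPCARNEQ array 3, 6 and 5 without siEGFP array 2, and 6 and 4 without siEGFP array 3. Heat shock genes that rose numbered 1 without siEGFP array 1 and 0 without siPCARNEQ array 3 or siEGFP array 2 or 3, and 3 fell without siEGFP array 2 or 3. NRF2 genes that fell numbered 2 without siPCARNEQ array 2 or 3 or siEGFP array 3. ATF4 targets that fell numbered 2 without siPCARNEQ array 3 and 3 without siPCARNEQ array 1 or 2 or siEGFP array 2 or 3. Of the NF-kB genes 0 rose without siPCARNEQ array 2 or 3, of the MAPK genes 2 fell without siEGFP array 2, and of the WNT genes 2 fell without siPCARNEQ array 1. In arrays 2 and 3 alone, 10 ATF4 targets rose and 11 fell.

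Metabolic and housekeeping lists stayed near 0 in the median. RPS25 fell by 0.61 and was the 1 of 51 ribosomal protein genes that changed (median -0.02, adjusted p = 0.618), while RPS27 had a change of 0.13 (adjusted p = 0.179). SDHD, a subunit of respiratory complex II, fell by 1.88 and NDUFA1 by 0.72 among 57 oxidative phosphorylation genes (2 rose, 8 fell, median 0.00, adjusted p = 0.575). The counts of that list were 10 that rose and 11 that fell in arrays 2 and 3 alone, 1 and 4 without siPCARNEQ array 2 or 3 or siEGFP array 2, 2 and 4 without siEGFP array 1, and 0 and 4 without siEGFP array 3. With arrays 2 and 3 averaged they were 0 and 2, or 2 and 4 when the array set was a block as well. PSMA3 and PSMD12 fell by 0.74 and 0.48 among 27 proteasome genes, a list with 0 that rose and 3 that fell (adjusted p = 0.0935, with 0 higher at an unadjusted p below 0.05 with limma). Without siEGFP array 2, 1 proteasome gene fell and PSMA3 did not pass (adjusted p = 0.0518), and neither PSMA3 nor PSMD12 passed with arrays 2 and 3 averaged (adjusted p = 0.0663 and 0.0614). PSMD12 had a change of -0.12 and did not pass when averaged over its probe sets (adjusted p = 0.155). INSIG1 and LSS rose by 0.78 and 0.62 among 19 cholesterol genes (2 rose, 0 fell, adjusted p = 0.575, with 1 lower at an unadjusted p below 0.05 with limma), and LSS did not pass with arrays 2 and 3 averaged (adjusted p = 0.0553), nor did SMS (adjusted p = 0.0531). ACSL4, with a change of -0.13 without probe sets that can match several transcripts, and GPAM fell 3.23-fold and 1.99-fold among 19 fatty acid genes (2 rose, 3 fell, adjusted p = 0.771), a list with a median of 0.11 and a mean of -0.01. In siPCARNEQ, ACSL4 lay at 6.32, below the array median of 7.03. SAT1, which starts polyamine breakdown, rose by 1.42 and SMS by 0.54 among 10 polyamine genes (2 rose, 1 fell, adjusted p = 0.575). Adjusted over the list alone, 2 oxidative phosphorylation genes rose and 4 fell, 2 fatty acid genes rose and 4 fell, and 5 polyamine genes rose and 3 fell, with the other counts of these lists as given. With the replicate number as a block, 6 proteasome genes fell, 3 cholesterol genes rose and 4 fell, 7 fatty acid genes rose and 3 fell, and 3 polyamine genes rose and 3 fell. With arrays 2 and 3 averaged and the array set as a block, 3 proteasome genes fell. The other counts there were 2 and 2 for cholesterol, 3 and 2 for fatty acid and 2 and 1 for polyamine genes. Without siPCARNEQ array 1, 5 cholesterol genes rose, and without siEGFP array 2 or 3, 1 fatty acid gene rose and 2 fell. Polyamine genes that fell numbered 2 without siPCARNEQ array 1 or 3 and 0 without siEGFP array 2 or 3.

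Other named genes passed but moved by over 1.5 times when averaged over all their probe sets. Among members of upward lists, MAF changed by 0.98, ALDH1A3 by 0.64, ACP3 by 0.97, CLDN4 by 0.22 and ERN1 by 0.27. CAD and NOP16 fell by 0.51 and 0.66, TMEM65 by 1.0, TNRC6A by 0.46, BCL2L11 by 0.60, GSK3B by 0.53, SDHD by 0.91, PSMA3 by 0.25, HSPA4 by 0.47, ACSL4 by 0.64 and SRSF10 by 0.43, while HNRNPU fell by 0.95. AGO4 rose by 0.60, CDKN1C by 0.78, COL1A1 by 0.49, ANKRD37 by 0.40, JDP2 by 0.39, KLF6 by 0.42, LUM by 0.67 and NCOA2 by 0.47. Without probe sets that can match several transcripts, ACP3 rose by 0.68, UGT2B15 fell by 0.49, TNRC6A fell by 0.59 and HSPD1 fell by 1.04.

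Of the 38 lists, 10 passed camera with the preset correlation, 4 upward and 6 downward. With an estimated correlation 1 passed, and 0 passed with an estimated correlation and the replicate number as a block. The block leaves so few residual degrees of freedom that 0 was close to fixed in advance and says little about any list. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, passed 17 lists, 7 upward and 10 downward. Besides the 10 lists above, these were, downward, RNA interference (adjusted p = 7.48e-05), pro-apoptotic (0.0347), MAPK (0.0347) and heat shock genes (0.0482). Upward they were polyamine (0.000173), autophagy (0.0432) and hypoxia genes (0.049).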

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

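The tests of the cell cycle lists, of androgen-induced members shared with other lists and of arrays numbered 1 were chosen after the results were seen, while the test against level-matched random lists was fixed before its result was seen.

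Probe sets outside the gene comparison, those with several genes or none listed, also carried signal. Of 13522 such probe sets, 1507 (11.1%) changed with limma at an adjusted p below 0.05, 856 upward and 651 downward, against 21% of single-gene probe sets and 0 of 62 control probe sets (1 at an unadjusted p below 0.05). The largest fall among them was in probe set 203359_s_at, at -3.19 (SE 0.16, adjusted p = 0.000134), from 11.76 in siEGFP to 8.57 in siPCARNEQ. The largest rise was in probe set 226809_at, at 2.54 (SE 0.21, adjusted p = 0.00045), from 9.29 to 11.83. No gene was named for either.

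Cell cycle genes were lower in siPCARNEQ cells with a preset correlation, while with an estimated correlation neither list passed (adjusted p = 0.359 for replication and 0.762 for mitosis, and 0.266 and 0.564 with the replicate block). The 3' bias of siPCARNEQ array 1 is argued against as the whole cause by arrays 2 and 3, where ACTB bias was alike in both groups and the median of mitosis genes was still -0.77. A smaller share of dividing cells after treatment with siRNA to PCARNEQ may underlie the pattern as a hypothesis, and an effect of the siRNA's own sequence on other transcripts stays open. Neither was tested: DNA content or nucleotide incorporation per cell would decide the share of dividing cells, and other siRNA sequences to PCARNEQ would decide the effect of sequence.

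Androgen-induced genes were higher in siPCARNEQ cells with a preset correlation, and the list did not pass with an estimated correlation (adjusted p = 0.114, and 0.324 with the replicate block). The 34 members held by no other list had a median of 0.31, with 14 that rose and 5 that fell, which argues against the shared members as the whole source. The list's median of 0.45 lay at percentile 100 of 10000 random lists matched on level, whose central 95% ran from -0.11 to 0.15, which argues against a normalization effect on abundant genes. Whether treatment with siRNA to PCARNEQ acts on androgen signalling could not be told from these arrays, and an indirect rise with slower growth stays open as well, since neither was tested.

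Array 1 stood apart in both groups, and compared with arrays 2 and 3 the 18S rRNA probe sets were higher by 1.17 in siPCARNEQ and 1.08 in siEGFP and the hybridization controls by 0.64 and 0.46, measures for which no explanation was tested. In siPCARNEQ array 1, the ACTB 3' to 5' difference exceeded that of arrays 2 and 3 by 1.15 and the GAPDH one by 0.37, and the added poly-A controls were higher by 1.29, so 3' bias and less sample RNA relative to the controls both remain possible explanations. In siEGFP array 1 the poly-A controls were higher by 0.09, which argues against less sample RNA relative to those controls there. It does not settle the amount of labelled cRNA on that array, where the hybridization controls were higher by 0.46. The ACTB excess of siEGFP array 1 was 0.13 and the GAPDH one 0.03, and 2 control genes are too few to settle 3' bias there. No biological explanation was tested, since the labels give arrays numbered 1 no condition of their own.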

How the results depend on the processing

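The counts with arrays 2 and 3 alone or averaged, with the array set as a block, with the ACTB covariate and with an estimated correlation plus block, and the comparison with other splits, were chosen after the data were seen. Signal over background was not measured by detection calls, so dim genes stayed in. Sorted values were already alike between arrays, so both rescaling alternatives moved almost nothing and say little about stability. Camera was not run with the intensity trend or with ordinary variance.

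Counts of changed probe sets (10122) moved by over 1.5 times with ordinary variance (6053), a fold change of at least 1.5 (5424), arrays 2 and 3 alone (17104), the array set as a block (15873) and arrays 2 and 3 averaged (2264), and ran from 5829 (without siEGFP array 2, and 5870 without array 3) to 13232 with 1 array left out. Counts of changed genes (5445) moved with arrays 2 and 3 alone (8229), averaged (2236) and a fold change of at least 1.5 (2509). They ran from 3701 to 6303 with 1 array left out, and 5165 changed with arrays 2 and 3 averaged and the array set as a block. Calls in that last setting rest mostly on variance that eBayes shares across genes. Averaging leaves 2 replicates per group, and 98 of the 117 named genes that passed still passed. Those genes were named for large changes or small p in these same arrays. Of all 5445 changed genes, 2236 still passed. With the replicate block 6834 genes and 12500 probe sets changed, and the interferon list passed (11 lists in all). That list did not pass with an estimated correlation and the block (adjusted p = 0.324). The block ended no list's call with the preset correlation and changed no named gene's call.

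Lists shifted numbered 10, from 9 to 12 with 1 array left out, 17 with fry, 1 with an estimated correlation and 0 with an estimated correlation and replicate block. An estimated correlation leaves the medians in place: androgen-induced 0.45, G1/S -0.68, mitosis -0.91, p53 -0.28, ER 0.17, junction 0.33, luminal 0.53, histone -0.29, splicing -0.25, all no longer passing, and with the block MYC targets at -0.56 too (adjusted p = 0.266). The estimate lay below the preset 0.01 for androgen-induced (-0.012), MYC (-0.029), ER (-0.035), luminal (-0.057), histone (-0.073) and splicing genes (-0.026). A higher correlation thus does not explain the weaker result of those lists. Camera with an estimated correlation rests on few residual degrees of freedom, and on fewer with the block. This weakens its result for every list. The p53 list did not pass without genes below the median level (-0.34), in arrays 2 and 3 alone (-0.24) or without siEGFP array 1 (-0.25; from -0.34 to -0.20 with 1 array left out), the histone list without genes below the median level (-0.22) and the splicing list without _x_at and _s_at probe sets (-0.11); the cause was not tested. Over 19 camera alternatives, adjusted p ran from 0.00253 to 0.327 for histones and from 0.000557 to 0.324 for splicing. Among list results in all, fry included, 711 kept their side, 24 weakened and 20 strengthened. Since fry asks a different question from camera, a list that passed only fry is not a stronger camera result.

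Named genes kept direction and side of the threshold in 2176 results, lost the call in 57, gained it in 4 and turned in 4: without _x_at and _s_at probe sets, another probe set stood for HSPA4 (0.46), SRSF10 (0.09), SRSF3 (0.01) and LUM (-0.06). Of the losses, 19 came with arrays 2 and 3 averaged (1 with the array set as a block too, BIRC2) and 12 with ordinary variance (ENO2, H1-3, H1-5, LOX, LSS, PLA2G2A, PSMA3, RNA45SN5, SEMA3C, SYT1, TGFB2 and UGT2B15), and the cause of the others was not tested.

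The 6 arrays form 10 splits into 3 and 3, too few for a share under 0.05. The real split alone, 1 of the 10, reached its own counts: 5445 genes with limma against 0 in every other split (76 to 772 at an unadjusted p below 0.05), 10122 probe sets against 0 (up to 2611) and 10 lists against 9. Every other split puts arrays of both treatments on each side, so a treatment difference adds to the spread within sides. Counts of 0 are then close to fixed in advance and say little about chance. The split with 9 lists had 0 changed genes, so lists can pass camera with the preset correlation where no gene passes. Among the 4 splits that part all 3 pairs, the others gave up to 6 lists. The 4 splits with both arrays 1 on the same side gave 9, 8, 6 and 6 lists and 364 to 772 genes at an unadjusted p below 0.05, and the 5 splits other than the real one that part the arrays 1 gave 2 to 6 lists and 76 to 206 genes.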

Other observations

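The gene families and single genes here were chosen after the data were seen, and their tests are descriptions of these arrays.

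Gene families defined by a shared symbol stem, with at least 6 measured genes, were compared with all genes for the share that rose or fell (529 families, 1058 1-sided Fisher's exact tests, Benjamini-Hochberg adjusted; genes of a family are not independent). Past the threshold were 14 tests, 13 for genes that fell and 1 for genes that rose, where 12.3% of all genes fell and 15.2% rose. All genes included dim ones. With genes below the median level left out, 2594 genes still rose and 2221 fell, against 3007 and 2438 over all genes. The shares among brighter genes are thus higher than 15.2% and 12.3%, and families were not compared with genes of a matched level. Mitochondrial ribosomal proteins fell in 20 of 50 genes of the large subunit (MRPL, adjusted p = 0.000389) and 12 of 27 of the small subunit (MRPS, adjusted p = 0.00485), beside 1 of 51 cytoplasmic ribosomal proteins, a difference that was not itself tested. RNA polymerase subunits (POLR) fell in 15 of 32, UTP nucleolar proteins in 7 of 10, exosome subunits (EXOSC) in 6 of 10, subunits of the CCT chaperonin in 6 of 9 and nucleoporins (NUP) in 10 of 26. Centrosomal CEP genes fell in 17 of 38, with 8 of 12 MCM, 6 of 7 CDCA, 5 of 7 HAUS, 14 of 42 KIF and 13 of 39 DDX genes. Genes with the stem RAB, which takes in the small RAB GTPases of membrane traffic and other genes named after them, rose in 27 of 71 (adjusted p = 0.000587, median 0.22). Genes of the VPS family rose in 14 of 38 (adjusted p = 0.0626), which did not pass.

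Single genes with large changes are given as values, and where a level lay below the array median of 7.03, as for HSD3B1 (4.80), HSD17B2 (5.32), SCGB1D2 (5.61), ANXA1 (5.80) and AKR1C3 (6.50) in siEGFP, it was not shown to be above background and the size of the change is uncertain. HSD3B1, a steroid dehydrogenase, rose by 2.29 (SE 0.20, adjusted p = 0.000308), CYP3A5 by 2.21 (SE 0.23), HSD17B2 by 1.55 and AKR1C3 by 1.54, while UGT2B28 fell by 2.45 (SE 0.29) and UGT2B17 by 1.36 (SE 0.34, adjusted p = 0.0218). Members of the UGT2B and AKR1C families are near-identical, so their single values are uncertain, and no list of steroid enzymes was tested. SCGB1D2 rose by 2.30, SLPI, a secreted protease inhibitor, by 1.84, and ANXA1 by 1.44. SOX9, a transcription factor of prostate epithelium, rose by 1.75, PRKCA by 2.29 and EIF2AK3, the ER stress kinase also called PERK, was 2.84-fold higher. In the E2F family, E2F5 fell by 2.03 (SE 0.24) beside E2F7, while E2F1 had a change of -0.10 (adjusted p = 0.496).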
